A study of Homo sapiens with 9 samples.

How the data were processed

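Gene expression was measured by RNA sequencing in A673, an established Ewing sarcoma cell line. Per the labels' protocols, cells were reverse transfected with 13 nM siRNA using a lipid reagent and RNA was isolated 48 h later from 3 independent experiments. Libraries were made from total RNA with the Illumina TruSeq RNA v2 kit, which does not mark strand. The 9 libraries form 3 groups of 3, taken from the labels: a scrambled siRNA and 2 siRNAs against LRWD1, named siLRWD1-5 and siLRWD1-6. The labels number the libraries of each group as series 1 to 3.

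The authors deposited a single table of raw read counts per gene symbol, with 1 column per library and no normalization. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.0.10 and HTSeq 0.5.4p3 were used with the hg19 genome build. The gene annotation, the counting mode and the strand setting are not given in the sources used here. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads of near-identical gene copies can be lost or assigned to the wrong copy. The table holds 23368 symbols, of which 4596 had no count in any library. No row lacked a gene name. None of the 13 mitochondrially encoded genes looked for by symbol was among the rows, so their share was not analysed here. The reference annotation used here is of another build, so no genomic coordinates are given.

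Total counts per library ranged from 11971179 to 15674452. Genes were kept with edgeR's filterByExpr, which left 13648 genes holding at least 99.92% of the counts of every library. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood fit with group as the only term and all 9 libraries in the fit. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 are called higher or lower. Standard errors (SE) of log2 fold changes were derived from the F statistic. Expression levels are given as TMM-scaled CPM, the count relative to the scaled library total.

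The rules in this paragraph were set before the data were examined. The groups compared were each siRNA against scrambled, siLRWD1-6 against siLRWD1-5, and the overlap of the comparisons against scrambled. The genes to be named were LRWD1, FLI1 and EWSR1, plus the genes with the largest changes past the threshold: 10 per direction for each siRNA and for the overlap (there ranked by the smaller change), and 5 per direction between the siRNAs. These needed a mean of at least 5 CPM and no overlap between the libraries of the groups, and uncharacterised, antisense and small RNA loci were left out. For each fixed gene list, up to 4 members past the threshold with the smallest p could be named, and any other member with its values. Results of some genes open to naming are not reported here. The 23 gene lists of 9 to 60 symbols were written from general knowledge, not from these samples, and 22 of them had at least 5 tested members. Lists were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Camera asks whether a list ranks apart from the other genes, whereas fry asks whether its genes move on balance in a direction.

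The fit was tested on simulated counts for the siLRWD1-5 comparison with 200 changed genes among the 13648. It recovered 58.2% of the genes changed by 0.5 on the log2 scale, 79.1% of those changed by 1 and 95.5% of those changed by 2, and 8.3% of its calls were unchanged genes. Alternatives were RLE size factors, no count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, fits with only the groups compared, and leaving out each library in turn. No scaling beyond library size, and a fit of only the libraries numbered 1 and 3 of each group, were added after seeing the data. Fold changes of unchanged groups against the same 3 control libraries were simulated 20 times.

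For the closing section, 7-base words were counted in the longest annotated 3' UTR of each gene in the GENCODE v29 transcripts (GRCh38), matched by symbol and older symbol. Of the tested genes, 11693 (85.7%) had a 3' UTR of at least 50 bases. Enrichment of each of the 16384 words in a gene set was expressed as a z from the hypergeometric mean and variance and compared with 100 random draws of equally many genes. Fold changes of all these genes were also regressed on each word with 3' UTR length and GC content as terms, with 100 permutations. In simulated fold changes with a planted word, the planted word ranked first in 5 of 5 trials. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.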

Results

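The series belongs to an RNA interference viability screen for targets in Ewing sarcoma cells carrying EWS-FLI1, the fusion of EWSR1 with the ETS factor FLI1. It addressed how the transcriptome of A673 cells, an established line of that tumour, changed after siRNA against LRWD1. LRWD1, also called ORCA, is a WD-repeat protein that binds the origin recognition complex, which marks where DNA replication starts. The 9 libraries were 3 with a scrambled siRNA, 3 with siLRWD1-5 and 3 with siLRWD1-6, each 48 h after transfection, and held between 11971179 and 15674452 counted reads.

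Replicates of a group differed from one another by more than sampling noise in every pair, with a chi-square per gene of 3.09 to 5.71 in the pairs that did not include scrambled replicate 2. That library differed from the other scrambled libraries by 30.03 and 25.64. Relative to them, its mitosis genes had a median log2 difference of -0.79, with 51 of 51 lower. Its DNA replication genes had a median of -0.57, its DNA damage response genes -0.53 and its cholesterol genes -0.52, whereas EWS-FLI1-repressed genes and growth factor and MAPK response genes had medians of 0.37.

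LRWD1 itself was lower in every siRNA library than in every scrambled library. It had 49.1, 54.6 and 49.3 CPM in the scrambled libraries, 10.6, 11.3 and 10.4 CPM with siLRWD1-5, and 6.55, 8.11 and 8.55 CPM with siLRWD1-6. This left 21.1% of its level with siLRWD1-5 (log2 fold change -2.24, SE 0.10, adjusted p = 9e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and 15.1% with siLRWD1-6 (log2 fold change -2.72, SE 0.11, adjusted p = 1.7e-07). The level was 28.4% lower with siLRWD1-6 than with siLRWD1-5 (adjusted p = 0.0058). FLI1, whose counts include reads of the fusion transcript, fell by 0.52 on the log2 scale with siLRWD1-5 (SE 0.08, adjusted p = 5e-04), and its annotated 3' UTR held 2 copies of 7-base words that were enriched among genes lower with that siRNA. With siLRWD1-6 its log2 fold change was 0.22 (SE 0.08, adjusted p = 0.082). That value was 0.30 and past the threshold without scrambled replicate 2, and 0.22 and past it with the replicate number as a block. EWSR1 did not pass the threshold with group as the only term, with log2 fold changes of -0.15 (adjusted p = 0.095) and -0.07 (adjusted p = 0.52). With the replicate number as a block, EWSR1 passed with siLRWD1-5 (-0.15).

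**Figure D1:**
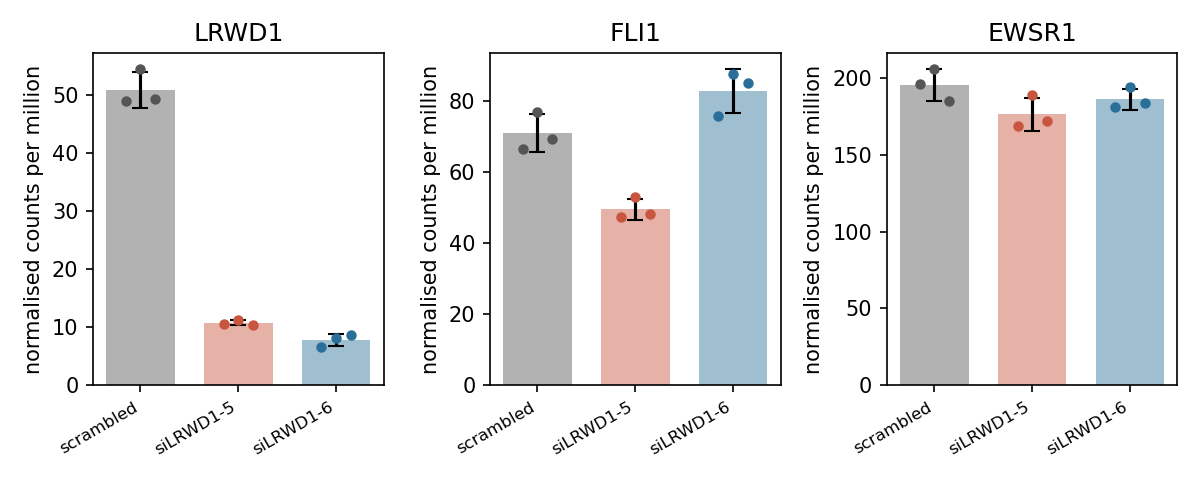
TMM-scaled CPM of LRWD1, FLI1 and EWSR1 in the 3 groups; points are libraries, bars are group means and error bars are SD (n = 3). LRWD1 lies at 49.1 to 54.6 CPM in the scrambled libraries and at or below 11.3 CPM in the siRNA libraries.

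siLRWD1-5 against scrambled addressed what the first siRNA changed. CLDN11, which encodes a tight junction claudin, rose most among the genes named by rule, from 1.10 ± 0.622 to 17.7 ± 3.98 CPM (SD, n = 3), a 15.5-fold increase (log2 fold change 3.96, SE 0.33, adjusted p = 9.1e-06). Cell junction genes F11R and DSP, encoding a tight junction adhesion molecule and desmoplakin, rose 6.06-fold and 5.36-fold. The transcription factor CEBPD rose 6.95-fold, the secreted pentraxin PTX3 rose 7.28-fold from 76.99 ± 58.5 to 557.8 ± 102 CPM, and the chemokine CXCL1 rose 6.28-fold. The tryptophan catabolism enzyme KYNU rose 7.55-fold, TNFAIP2 7.49-fold, the cytokine LIF 5.71-fold and the costimulatory ligand ICOSLG 5.02-fold. PRDX3, a mitochondrial peroxidase, fell most, from 235.6 ± 17.3 to 28.1 ± 2.03 CPM, which was 8.39-fold lower (log2 fold change -3.07, SE 0.08, adjusted p = 3e-09). CMC2, a mitochondrial protein, was 5.74-fold lower, GGCT 5.57-fold, EI24 5.32-fold, ARL6IP6 5.24-fold and the scavenger receptor COLEC12 4.77-fold. The neurotrophin receptor NGFR was 5.79-fold lower and the matrix protein SPP1 6.05-fold. FAM45B was 7.31-fold lower, which is uncertain because reads can be shared with its near-identical copy FAM45A. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, these genes had adjusted p-values from 3e-09 to 0.031. The 3' UTRs of PRDX3, NGFR, CMC2, GGCT, EI24 and ARL6IP6 held 7-base words that were enriched among genes lower with siLRWD1-5. In all, 2527 genes were higher and 2765 lower, 38.8% of the 13648 tested, and 445 and 443 of these changed at least 2-fold. They numbered 3326 and 3464 without scrambled replicate 2. LIF lost its call without scrambled replicate 1 (log2 fold change 2.03), scrambled replicate 3 (2.08) or siLRWD1-5 replicate 2 (2.07), and with no filter on low counts or only these groups in the fit (both 2.52). SPP1 lost its call without siLRWD1-5 replicate 1 (-2.42). In the scrambled libraries SPP1, LIF and KYNU had 18.75 ± 17.7, 9.52 ± 11.9 and 3.91 ± 4.3 CPM (SD, n = 3), so their folds rest on uneven controls. With siLRWD1-6 SPP1 was also lower than in scrambled, by 4.16-fold, short of the threshold (edgeR, adjusted p = 0.063).

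Among the fixed lists, genes activated by EWS-FLI1 ranked lower with siLRWD1-5 (camera, adjusted p = 0.00049, and adjusted p = 0.66 with an estimated correlation). Of 39 tested, 19 fell and 2 rose, also when adjusted over the list alone, with a median log2 fold change of -0.43, and 24 fell and 4 rose without scrambled replicate 2. They included the metalloreductase gene STEAP2 (2.50-fold lower), CAV1, encoding caveolin (2.57-fold lower), the netrin receptor DCC (1.94-fold lower) and RBM11 (1.77-fold lower). Genes repressed by EWS-FLI1 had a median of 0.42, with 9 of 33 higher and 5 lower, and were not called (adjusted p = 0.19). RUNX2 rose 2.74-fold and SPRY1 2.82-fold, whereas SPRY4 was 1.85-fold lower. In scrambled replicate 2 this list had a median of 0.37 relative to the other scrambled libraries, and without it 17 genes were higher and 5 lower and the list was called higher (adjusted p = 0.023, and adjusted p = 0.62 with an estimated correlation). Nuclear genes of oxidative phosphorylation ranked lower (adjusted p = 0.00049, and adjusted p = 0.95 with an estimated correlation), with 18 of 36 lower and 0 higher, also when adjusted over the list alone. COX4I1, SDHC and ATP5D, which encode subunits of complexes of the respiratory chain and the ATP synthase, were 2.12-fold, 2.27-fold and 2.09-fold lower. Genes of the origin recognition complex and LRWD1 partners ranked lower (adjusted p = 0.042, and adjusted p = 0.99 with an estimated correlation), with 5 of 9 lower, also when adjusted over the list alone. ORC2 was 1.45-fold lower, ORC5 1.53-fold and CDC6, a licensing factor, 1.98-fold. The 3' UTRs of 4 of the 9 genes held 7-base words enriched among genes lower with siLRWD1-5 (44.4%, against 24.9% of all genes with a 3' UTR), and these had a median of -0.58 against -0.29 for the others. Of the 5 genes called lower, 3 held a word. This list had a median of -0.50 in scrambled replicate 2 relative to the other scrambled libraries. When that library was left out, 8 of 9 genes were lower, with a median of -0.55 (adjusted p = 0.00015, and adjusted p = 0.31 with an estimated correlation). The call was lost without scrambled replicate 1, scrambled replicate 3, siLRWD1-5 replicate 2 or siLRWD1-5 replicate 3, with medians of -0.48, -0.47, -0.45 and -0.55. It was also lost with no scaling beyond library size, a setting chosen after seeing the data (median -0.46).

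Genes of the unfolded protein response of the endoplasmic reticulum ranked higher with siLRWD1-5 (adjusted p = 0.011, and adjusted p = 0.99 with an estimated correlation). Of 25 tested, 14 rose and 2 fell, or 15 and 2 adjusted over the list alone, with DNAJB11 1.35-fold and PDIA6 1.34-fold higher. Interferon response genes ranked higher (adjusted p = 0.017, and adjusted p = 0.38 with an estimated correlation), with 13 of 36 higher and 4 lower, also when adjusted over the list alone. The ADP-ribosyltransferase genes PARP14 and PARP9 rose 1.93-fold and 1.90-fold, and the transcription factor IRF1 rose 2.63-fold. Camera with an estimated correlation called 0 lists for siLRWD1-5, so none of the 5 calls held in that test. For the interferon list the estimate was 0.0031, under the preset 0.01. Its lost call therefore cannot come from a higher correlation among its own genes. Fry, which asks another question, called the 5 lists in the same directions. It gave adjusted p = 0.0011 for EWS-FLI1-activated genes, 0.001 for oxidative phosphorylation, 0.014 for the origin recognition complex list, 0.011 for the unfolded protein response and 0.00044 for interferon response. With scrambled replicate 2 left out, the preset correlation gave adjusted p = 8.5e-05 for EWS-FLI1-activated genes, 0.002 for oxidative phosphorylation, 0.00048 for the unfolded protein response and 0.021 for interferon response. The estimated correlation then gave adjusted p = 0.60, 0.60, 0.60 and 0.31.

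The other lists were not called with siLRWD1-5 by camera, whereas fry, which does not compare a list with other genes, called neural genes (adjusted p = 0.011) and ATF4 and amino acid response genes (adjusted p = 0.014) lower. Of 50 DNA replication genes, 14 were lower and 0 higher (adjusted p = 0.19), among them RFC2 (1.89-fold lower). Of 51 mitosis genes, 7 were lower and 0 higher, or 4 and 0 adjusted over the list alone (adjusted p = 0.58), among them CDC20, an activator of the anaphase-promoting complex, which was 4.11-fold lower. Of 44 DNA damage response and repair genes, 10 were lower and 1 higher, or 9 and 1 adjusted over the list alone (adjusted p = 0.35), and TOPBP1 and the checkpoint kinase CHEK1 were 2.27-fold and 1.88-fold lower. Without scrambled replicate 2, in which these 3 lists were low, they ranked lower, with 34, 31 and 27 members lower and 0, 1 and 1 higher (adjusted p = 6.4e-09, 8.2e-08 and 7e-05). With an estimated correlation that fit gave adjusted p = 0.60 for each. Without that library, the extracellular matrix and cytoskeleton list was also called higher (adjusted p = 0.036, and adjusted p = 0.67 with an estimated correlation). ATF4 and amino acid response genes had 3 higher and 10 lower of 34 (adjusted p = 0.54), p53 targets 7 and 6 of 27 (0.97), apoptosis regulators 8 and 4 of 31 (0.54), and cholesterol synthesis and uptake 8 and 2 of 34 (0.54). The cholesterol list had a median of -0.52 in scrambled replicate 2 relative to the other scrambled libraries, and leaving that library out turned its direction, with 7 higher, 12 lower and a median of -0.13 in place of 0.05 (adjusted p = 0.53). Hypoxia and glycolysis genes had 7 higher and 9 lower of 31 (0.97), heterochromatin and DNA methylation factors 5 and 5 of 32 (0.97), ribosome biogenesis 1 and 9 of 45 (0.19), and extracellular matrix and cytoskeleton 19 and 12 of 58 (0.19). Neural genes had 4 higher and 8 lower of 24 (0.55), growth factor and MAPK response genes 7 and 9 of 41 (0.66), IGF1 and insulin signalling 11 and 5 of 31 (0.58), and the small RNA pathway 4 and 6 of 17 (0.86). The fit without scrambled replicate 2 also gave 15 higher and 10 lower MAPK genes, 7 and 13 heterochromatin genes, 15 and 5 apoptosis regulators, 5 and 15 ATF4 genes, 5 and 11 ribosome biogenesis genes, 2 and 7 small RNA pathway genes and 2 and 1 markers of other cell types. Camera did not call these lists in it. Adjusted over the list alone, the counts were the same except for 10 lower hypoxia genes, 21 higher matrix genes, 9 lower neural genes and 11 lower MAPK genes. The MAPK list had a median of -0.06, a mean of 0.13 and the direction lower by camera, the p53 list a median of 0.02, a mean of 0.03 and the direction lower, and the heterochromatin list a median of 0.01, a mean of -0.01 and the direction higher. Of 25 markers of other cell types, 6 were expressed enough to be tested and 0 passed the edgeR threshold, with or without adjustment over the list alone (list adjusted p = 0.97). At an unadjusted p under 0.05, 1 of them passed, and DESeq2 called 1 and limma-voom 0. CD68 had the highest mean level of these markers, 34.2 CPM.

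siLRWD1-6 against scrambled addressed what the second siRNA changed. The genes that rose most were VLDLR, a lipoprotein receptor gene, from 1.99 ± 0.367 to 12.9 ± 0.881 CPM (SD, n = 3; 6.38-fold, log2 fold change 2.67, SE 0.17, adjusted p = 3.9e-06), and DDIT4, an inhibitor of mTORC1 signalling (5.37-fold). The mitochondrial enzyme gene PCK2 rose 4.75-fold and CHAC1, whose product degrades glutathione, rose 4.60-fold. VLDLR, DDIT4, PCK2 and CHAC1 are members of the fixed ATF4 list. The matrilin gene MATN2 rose 3.44-fold, the natriuretic peptide receptor gene NPR3 3.18-fold, FAM114A1 2.88-fold, PDCD4 2.77-fold, the retrieval receptor gene KDELR3 2.64-fold and the peptide hormone gene ADM2 2.63-fold. Besides LRWD1, the metalloproteinase inhibitor TIMP2 fell most, from 678.8 ± 59.5 to 148.6 ± 9.36 CPM, which was 4.57-fold lower (log2 fold change -2.19, SE 0.08, adjusted p = 1.7e-07). MFSD1 was 4.20-fold lower, WSB2 3.50-fold, LSMD1 3.36-fold, NT5C3L 3.32-fold, the pyrophosphate transporter gene ANKH 3.25-fold, CDCA7L 3.13-fold, the growth factor gene PGF 3.07-fold and CMTM6 2.97-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, these genes had adjusted p-values from 1.7e-07 to 0.0098. The 3' UTRs of MFSD1, ANKH, CDCA7L and CMTM6 held 7-base words that were enriched among genes lower with siLRWD1-6. In all, 1203 genes were higher and 1062 lower, 16.6% of those tested, and 78 and 108 of these changed at least 2-fold. Leaving out scrambled replicate 2 gave 2115 and 1838, and leaving out siLRWD1-6 replicate 1 gave 702 and 546. Leaving out siLRWD1-6 replicate 2 gave 763 and 606, leaving out siLRWD1-6 replicate 3 gave 613 lower genes, and fitting only these groups gave 696 lower genes.

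The ATF4 and amino acid response list, genes that respond to amino acid shortage and to other stresses that block translation initiation, ranked higher with siLRWD1-6 (camera, adjusted p = 1.6e-58). Of 34 tested, 29 rose and 0 fell, or 31 and 0 adjusted over the list alone, with a median log2 fold change of 0.79. ASNS, encoding asparagine synthetase, rose 2.63-fold and PYCR1, encoding an enzyme of proline synthesis, rose 1.76-fold. This call held with an estimated correlation (adjusted p = 0.00056). A fit of only the libraries numbered 1 and 3 of each group was chosen after seeing the data. In it 33 genes of the list were higher and 0 lower, with a median of 0.80. Camera gave adjusted p = 6.8e-61 there with the preset correlation, but the call was lost with an estimated correlation (adjusted p = 0.11). With all libraries, the unfolded protein response list ranked higher (adjusted p = 1e-14, and adjusted p = 0.10 with an estimated correlation), with 17 of 25 higher and 0 lower, or 19 and 0 adjusted over the list alone. The chaperone gene HSPA5 rose 1.84-fold, the transcription factor gene XBP1 1.64-fold and SEC24D 1.73-fold. Cholesterol synthesis and uptake genes ranked higher (adjusted p = 1.8e-06, and adjusted p = 0.80 with an estimated correlation), with 15 of 34 higher and 1 lower, or 18 and 1 adjusted over the list alone. SQLE, encoding an enzyme of the pathway, rose 1.72-fold, whereas SC5DL, encoding a later enzyme, was 1.8-fold lower. In scrambled replicate 2 this list had a median of -0.52 relative to the other scrambled libraries, and without it the list still ranked higher (adjusted p = 0.0012, and adjusted p = 0.52 with an estimated correlation). p53 targets were called higher (adjusted p = 0.037, and adjusted p = 0.33 with an estimated correlation) with 7 of 27 higher and 0 lower, or 7 and 1 adjusted over the list alone. Of these, SESN2 (2.36-fold) is also in the ATF4 list, and GDF15 (2.56-fold) is known to respond to ATF4 as well. This call was lost without scrambled replicate 1 or scrambled replicate 3, with list medians of 0.00 and 0.04, and by limma-voom, with a median of 0.05.

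Interferon response genes ranked lower with siLRWD1-6 (adjusted p = 0.0018, and adjusted p = 0.10 with an estimated correlation), with 11 of 36 lower and 2 higher, or 15 and 2 adjusted over the list alone. IFI44 was 1.64-fold lower and CMPK2 2.25-fold, whereas IRF1 rose 1.67-fold. Oxidative phosphorylation genes ranked lower (adjusted p = 0.0056, and adjusted p = 0.75 with an estimated correlation), with 8 of 36 lower and 0 higher, or 10 and 0 adjusted over the list alone, and NDUFV1 and CYC1 were 1.24-fold and 1.20-fold lower. Of the 6 called lists, ATF4 and amino acid response alone held with an estimated correlation. The interferon list lost its call although its estimate, 0.0074, was under the preset 0.01. Of the same lists, fry did not call cholesterol synthesis and uptake (adjusted p = 0.13). It called the others in the same directions, with adjusted p = 2e-06 for ATF4 and amino acid response and 0.00048 for the unfolded protein response. For p53 targets, interferon response and oxidative phosphorylation fry gave adjusted p = 0.008, 0.00045 and 0.016.

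The other lists were not called with siLRWD1-6 by camera. Fry called neural genes (adjusted p = 0.0053) and markers of other cell types (adjusted p = 0.048) lower. EWS-FLI1-activated genes had 2 of 39 higher and 5 lower (adjusted p = 0.27), or 7 and 10 without scrambled replicate 2 (adjusted p = 0.14). IL1RAP rose 1.74-fold, and PRKCB and SOX2 were 1.49-fold and 1.42-fold lower. EWS-FLI1-repressed genes had 7 of 33 higher and 0 lower, or 7 and 1 adjusted over the list alone (adjusted p = 0.12), with COL5A1 1.75-fold and LOX 1.63-fold higher. In scrambled replicate 2 the repressed list had a median of 0.37 relative to the other scrambled libraries. Of 50 DNA replication genes, TIPIN, CCNE2, RRM2 and CHAF1B were lower (1.51-fold, 2.07-fold, 1.54-fold and 1.33-fold) and 0 higher, or 2 lower adjusted over the list alone (adjusted p = 0.23). TIPIN kept its call in each fit that left out a library. CCNE2 lost it without siLRWD1-6 replicate 3 (-0.90 on the log2 scale). RRM2 lost it, at -0.64 to -0.47, without scrambled replicate 1 or 3, siLRWD1-5 replicate 2 or 3, or any siLRWD1-6 replicate, and CHAF1B, at -0.42 to -0.32, in each fit that left out a library other than scrambled replicate 2. Of 51 mitosis genes, 0 passed the edgeR threshold (list adjusted p = 0.79), and of the 9 genes of the origin recognition complex list 0 passed (0.55), also when adjusted over the list alone. For both lists 0 genes passed at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Of 44 DNA damage response genes, RAD51C was 1.2-fold lower by edgeR and 0 were called by DESeq2 (list adjusted p = 0.98). RAD51C lost its call, at -0.27 to -0.23, without scrambled replicate 1 or 3, siLRWD1-5 replicate 2 or any siLRWD1-6 replicate. Without scrambled replicate 2, in which these lists were low, 32 DNA replication genes, 29 mitosis genes, 15 DNA damage response genes and 4 genes of the origin recognition complex list were lower, and the lists were called (adjusted p = 1.7e-11, 1.8e-07, 0.0025 and 0.025). With an estimated correlation that fit gave adjusted p = 0.42, 0.50, 0.50 and 0.42. Without that library EWS-FLI1-repressed genes (0.0053), extracellular matrix genes (0.044) and growth factor and MAPK response genes (0.0025) were also called higher and neural genes lower (0.02). These calls were lost with an estimated correlation (adjusted p = 0.50, 0.52, 0.50 and 0.16), whereas the unfolded protein response call held in that fit (adjusted p = 0.04). In it the genes higher and lower numbered 13 and 3 for the EWS-FLI1-repressed list, 19 and 5 for MAPK, 5 and 10 for neural, 7 and 7 for heterochromatin, 9 and 4 for ribosome biogenesis, 8 and 6 for IGF1 signalling and 3 and 0 for small RNA pathway genes. They were 9 and 3 for p53 targets, 16 and 3 for cholesterol genes, 1 and 9 for oxidative phosphorylation and 1 and 2 for markers of other cell types. With all libraries, neural genes had 3 higher and 9 lower of 24 (0.072), among them GAP43 (2.42-fold lower), and matrix genes 14 and 5 of 58 (0.27). MAPK response genes had 7 higher and 3 lower of 41 (0.27), apoptosis regulators 7 and 3 of 31 (0.55), hypoxia and glycolysis 8 and 3 of 31 (0.41), with VEGFA 1.90-fold higher, and IGF1 and insulin signalling 8 and 1 of 31 (0.41). Ribosome biogenesis had 4 higher and 2 lower of 45 (0.79), heterochromatin factors 1 and 0 of 32 (0.61), and the small RNA pathway 1 and 0 of 17 (0.34). The histone demethylase gene KDM4A was 1.14-fold higher and lost its call, at 0.16 to 0.23 on the log2 scale, in each fit that left out a library other than scrambled replicate 2. The small RNA pathway gene TNRC6A was 1.53-fold higher. Adjusted over the list alone, the counts were 5 and 10 for neural genes, 16 and 5 for matrix genes, 8 and 4 for MAPK genes, 7 and 4 for apoptosis regulators, 9 and 4 for hypoxia genes and 0 for heterochromatin factors and DNA damage response genes, of which 8 and 3 passed at an unadjusted p under 0.05. DESeq2 called 2 and 0 of these lists' genes, and limma-voom 1 and 1. The mitosis list had a median of -0.01 and the direction higher by camera, as had the DNA damage list, and IGF1 signalling had a median of 0.02 and a mean of -0.04. Of the 6 tested markers of other cell types, PDGFRA and KDR were 2.31-fold and 2.42-fold lower, or 3 genes were lower adjusted over the list alone (list adjusted p = 0.34). PDGFRA lost its call without siLRWD1-6 replicate 2 (-1.07), and KDR without siLRWD1-6 replicate 1, 2 or 3 (-1.32, -1.36 and -1.14). With only these groups in the fit, RRM2 (-0.61), CHAF1B (-0.40), KDM4A (0.20), RAD51C (-0.25) and KDR (-1.27) were not called, and with no filter on low counts RRM2, KDM4A and RAD51C were not, at the same values. CHAF1B was not called by limma-voom (-0.40).

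**Figure D2:**
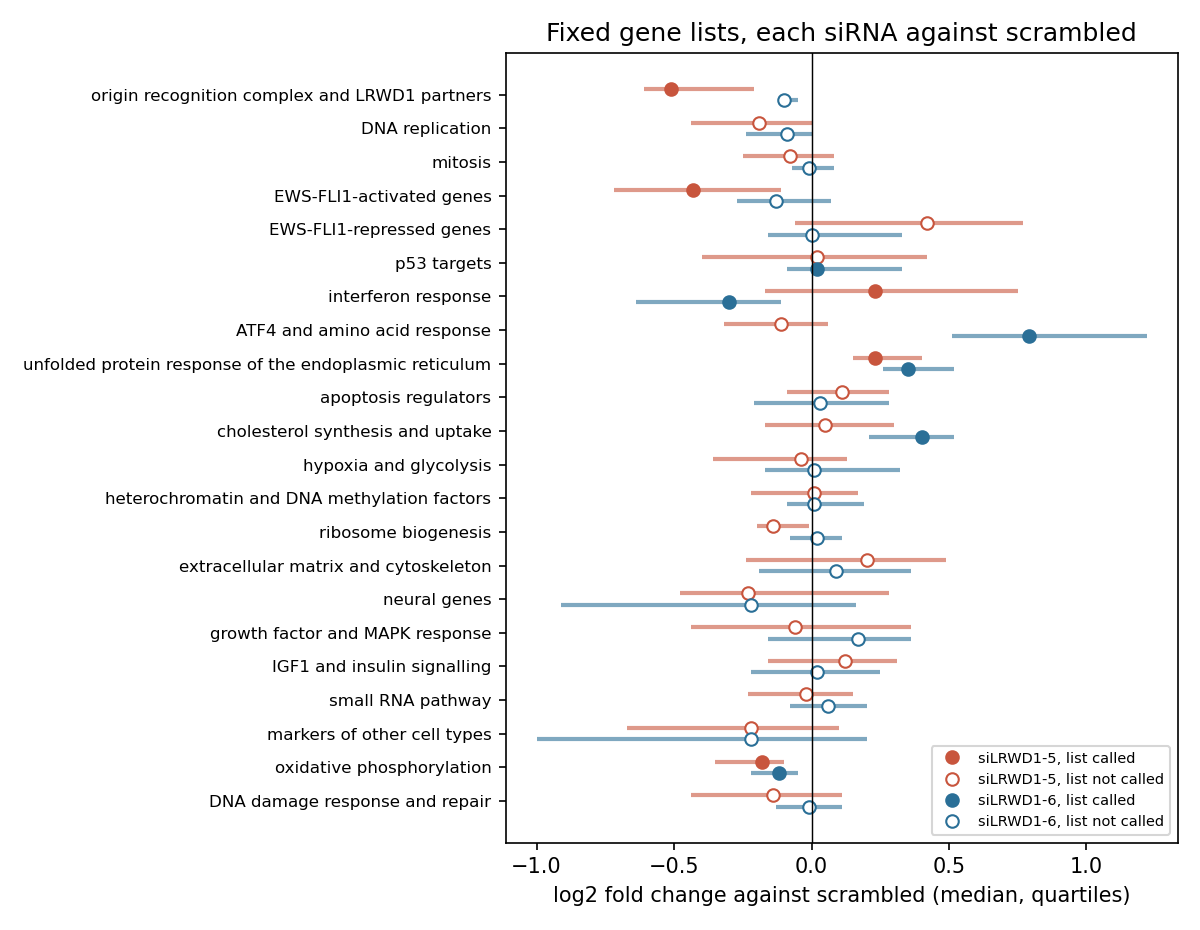
Median log2 fold change of the tested genes of each fixed list against scrambled, with siLRWD1-5 and siLRWD1-6 in separate colours; lines span the quartiles and filled points are lists called by camera at an adjusted p under 0.05 with the preset correlation. The ATF4 and amino acid response list has a median of 0.79 with siLRWD1-6 and -0.11 with siLRWD1-5.

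siLRWD1-6 against siLRWD1-5 tested directly where the siRNAs against the same gene differed. The ATF4 and amino acid response genes were higher with siLRWD1-6, with 29 of 34 higher and 0 lower, also when adjusted over the list alone, and a median log2 difference of 1.04 (adjusted p = 1.9e-25, and 0.0036 with an estimated correlation). ATF4 itself was 2.61-fold higher. Interferon response genes were lower with siLRWD1-6, with 22 of 36 lower and 1 higher, or 25 and 1 adjusted over the list alone (adjusted p = 1.3e-05, and 0.023 with an estimated correlation), and PARP9 was 2.54-fold lower. In the fit of only the libraries numbered 1 and 3 of each group, chosen after seeing the data, the ATF4 and interferon calls were lost with an estimated correlation (adjusted p = 0.28 and adjusted p = 0.39). The medians in it were 1.07 and -0.57, with 29 ATF4 genes higher and 0 lower, and 1 interferon gene higher and 22 lower. Camera with the preset correlation still called both lists (adjusted p = 8.2e-29 and 0.00011). EWS-FLI1-activated genes were higher with siLRWD1-6, with 18 of 39 higher and 3 lower, or 20 and 3 adjusted over the list alone (adjusted p = 0.026, and 0.94 with an estimated correlation). This call was lost without siLRWD1-5 replicate 2, with a median of 0.25 against 0.26, and leaving out scrambled replicate 2 gave 23 higher and 6 lower. Camera called no other list, although without scrambled replicate 2 cholesterol genes were called higher with siLRWD1-6 (adjusted p = 0.0056, and adjusted p = 0.82 with an estimated correlation). Fry also called the origin recognition complex (adjusted p = 0.03), p53 (0.004), unfolded protein response (0.019) and oxidative phosphorylation (0.015) lists higher with siLRWD1-6. The p53 list had a median of -0.05, a mean of 0.16 and the direction higher, the MAPK list a median of 0.10 and a mean of -0.12, and the markers of other cell types a median of 0.05 and the direction lower. Of these markers KDR was 3.14-fold lower, PDGFRA 2.21-fold lower, CD68 1.46-fold lower and CLDN4 2.54-fold higher with siLRWD1-6. FLI1 was 1.67-fold higher with siLRWD1-6 (adjusted p = 3e-05). KYNU, CLDN11, CXCL1, ADAMTS9 and CEBPD were 34.2-fold, 18.4-fold, 13.7-fold, 11.5-fold and 8.72-fold lower with siLRWD1-6, although none was called with siLRWD1-6 against scrambled. KYNU, CLDN11, CXCL1 and ADAMTS9 had means of only 0.83, 0.95, 1.78 and 1.28 CPM with siLRWD1-6. The size of their folds is therefore uncertain (SE 0.79, 0.34, 0.53 and 0.94 on the log2 scale). ADAMTS9 lost its call between the siRNAs without siLRWD1-6 replicate 1 or siLRWD1-6 replicate 3, with log2 fold changes of -3.42 and -3.27. COLEC12, FAM45B, CHAC1, PRDX3 and HIST1H2BD were 8.01-fold, 7.88-fold, 7.49-fold, 6.83-fold and 5.88-fold higher. HIST1H2BD belongs to a family of similar histone genes, so its counts are uncertain. The adjusted p of these 10 genes ranged from 2.4e-09 to 0.018 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 3063 genes were higher and 2856 lower with siLRWD1-6 by edgeR, 43.4% of those tested, so that 51.7% of the calls were higher. Leaving out scrambled replicate 2 gave 3954 and 3597. With no scaling beyond library size, a setting chosen after seeing the data, 2478 were higher and 3609 lower, or 40.7% higher.

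The overlap of the comparisons against scrambled addressed what both siRNAs changed alike. KDELR3 rose 2.60-fold with siLRWD1-5 and 2.64-fold with siLRWD1-6, the endothelin-converting enzyme gene ECE2 2.63-fold and 2.51-fold, and the lipid transporter gene MFSD2A 2.25-fold and 2.57-fold. EFNA1, encoding an ephrin, rose 4.51-fold and 2.17-fold, SELM 3.78-fold and 2.17-fold, DRAM1 3.02-fold and 2.14-fold, MAGEH1 2.36-fold and 2.15-fold, and FAM73A 2.23-fold and 2.08-fold. MATN2 rose 2.19-fold with siLRWD1-5 and PDCD4 2.11-fold, beside the rises with siLRWD1-6 given above. Besides LRWD1, PLS3, encoding the actin-bundling protein plastin, was 4.0-fold and 2.72-fold lower, and the urotensin gene UTS2 was 3.14-fold and 1.97-fold lower. The neuronal growth-cone gene GAP43 was 2.01-fold and 2.42-fold lower, the calcium channel gene CACNA1G 1.98-fold and 2.27-fold, PKIA 2.42-fold and 1.90-fold, and the G-protein regulator gene RGS4 1.99-fold and 1.89-fold. SEPT9, encoding a septin, was 1.85-fold and 1.89-fold lower, and RNF114 1.76-fold and 1.84-fold. PKIA lost its siLRWD1-6 call without siLRWD1-6 replicate 1 (-0.87 on the log2 scale) or siLRWD1-6 replicate 3 (-0.88). A fit with only the groups compared ended the same call (-0.92). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the genes named here besides LRWD1 had adjusted p-values from 1.2e-08 to 0.01 with siLRWD1-5 and from 4.7e-07 to 0.015 with siLRWD1-6. The 3' UTRs of MATN2, DRAM1 and PDCD4 held 7-base words enriched among genes higher with both siRNAs. These were 3 of the 8 named higher genes with a 3' UTR, against 26.1% of all genes with one, so no enrichment is claimed for the named genes. The 3' UTRs of PLS3, PKIA and RNF114 held words enriched among genes lower with each siRNA, and those of RGS4 and SEPT9 words enriched among genes lower with siLRWD1-5. PKIA and RNF114, although lower, also held 1 copy each of a word enriched among genes higher with both.

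In all, 496 genes were higher and 323 lower with both siRNAs, where independent lists of these sizes would share 222.7 and 215.2. Another 386 passed in opposite directions, 171 higher with siLRWD1-5 and 215 lower with it, where independent lists would share 196.6 and 243.7. All 386 also passed the direct test between the siRNAs, which their choice by opposite calls in the same fit made nearly certain. At least 2-fold changes with both siRNAs were found for 18 higher and 7 lower genes. Without scrambled replicate 2 the numbers were 966, 784 and 685, and without siLRWD1-6 replicate 1 they were 304, 169 and 196. Leaving out siLRWD1-6 replicate 2 gave 186 lower and 217 opposite genes, leaving out siLRWD1-6 replicate 3 gave 175 and 253, and leaving out scrambled replicate 1 gave 241 opposite genes. Fits with only the groups compared gave 186 lower and 227 opposite genes. Across the 13648 genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.131 and a Spearman rho of 0.165. The r was 0.209 without scrambled replicate 1 and 0.241 without scrambled replicate 2. It was 0.352 with no filter on low counts and 0.311 with DESeq2, which was also run without that filter. These values cover more genes than the 13648, and limma-voom on the filtered genes gave 0.133. Simulated unchanged groups against the same controls gave a mean r of 0.498 and 0 genes higher and 0.1 lower in both, but unchanged groups have hardly any calls to share. The covariance was 0.0257, against a simulated mean of 0.021, a difference of 0.00464. The simulation gave every group the same spread per gene. The real scrambled libraries deviated more from the others of their group (SD over genes of 0.32, 0.46 and 0.30 on the log2 scale) than the siRNA libraries (0.23 to 0.25). The simulation may therefore understate the covariance from shared controls, and no conclusion is drawn from the difference. The 3 control libraries are too few to be split, so part of the excess over independent lists may come from the shared controls.

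**Figure D3:**
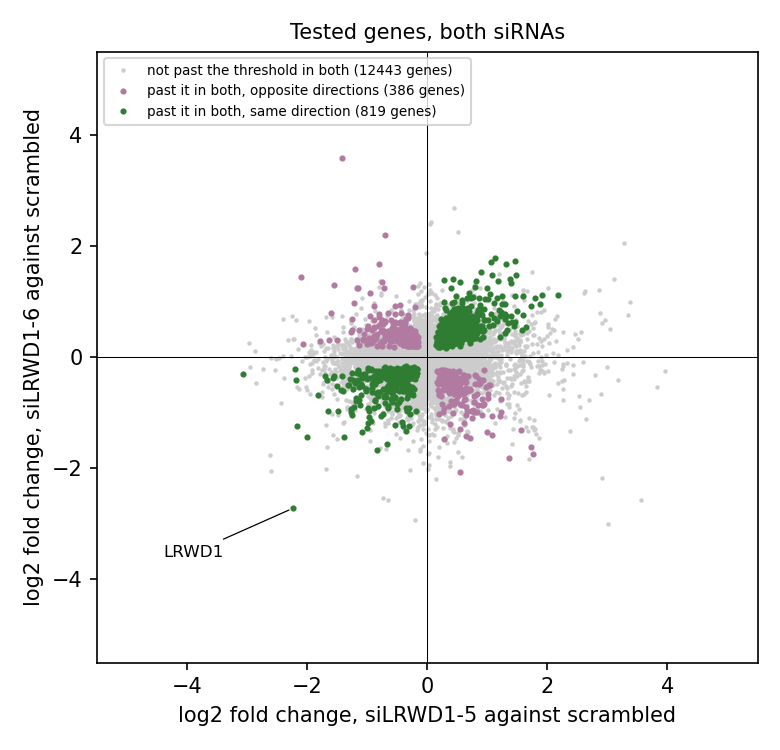
Log2 fold change of each tested gene with siLRWD1-5 (x axis) and siLRWD1-6 (y axis) against scrambled; coloured points passed the edgeR threshold in both comparisons. Of these, 819 changed in the same direction and 386 in opposite directions, and LRWD1 lies at -2.24 and -2.72.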

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

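The tests on 3' UTR length and base composition, on loss of LRWD1 and on the scrambled siRNA, as well as the fits without each library for the words, were chosen only after the results were seen; the word counts for each siRNA and the regroupings of the libraries were planned. The results flagged here differ between the siRNAs by a direct test in the same fit. They are LRWD1 (log2 difference of siLRWD1-6 against siLRWD1-5 of -0.48), FLI1 (0.74), and the medians of the ATF4 and amino acid response list (1.04), the interferon response list (-0.62) and the EWS-FLI1-activated list (0.26). The call of the EWS-FLI1-activated list was lost with an estimated correlation (adjusted p = 0.94) and without siLRWD1-5 replicate 2 (median 0.25). The calls of the ATF4 and interferon lists held with an estimated correlation over all libraries (adjusted p = 0.0036 and 0.023) but not in a fit of only the libraries numbered 1 and 3 of each group, which was also chosen after the results were seen (adjusted p = 0.28 and 0.39). The medians in that fit were 1.07 and -0.57, and camera with the preset correlation still called both lists (adjusted p = 8.2e-29 and 0.00011). Single outlying libraries were not tested in these groups of 3, although scrambled replicate 2 differed from the others of its group by a chi-square per gene of 30.03 and 25.64, against 3.09 to 5.71 in the pairs without it.

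Genes lower with siLRWD1-5 shared a sequence word. Loss of LRWD1 as the whole cause is argued against by the same 2764 genes with siLRWD1-6, where their median log2 fold change was -0.05 (-0.05 to -0.04 over leaving out each library) against -0.51 with siLRWD1-5, although LRWD1 was lower with siLRWD1-6. The genes were chosen as lower with siLRWD1-5 in the same data, which favours a gap of untested size, and the range keeps that choice fixed. An annotated 3' UTR was found for 2450 of the 2765 genes, and 819 of them (33.4%) held CCTGAAA where 453.4 were expected, a z of 21.4 against at most 4.9 in 100 draws, and 3' UTR length and base composition are argued against by a z of -18.6 with both in the regression (lowest of the permutations, -4.8). The word with the next rank extends it to ACCTGAAA, which occurs in the coding part of LRWD1 (base 478 of the 2215-base main transcript in GENCODE v29, coding from base 153 to 2093), and genes with that site had a median of -0.28 with siLRWD1-5 and 0.02 with siLRWD1-6. Silencing through seed matches, the pairing of the first bases of the siRNA with 3' UTRs, is therefore a candidate explanation for part of these genes, while the cause of the change in genes without the word stays open and the siRNA sequences were not used here.

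Genes lower with siLRWD1-6 showed the same pattern with another word and in fewer genes. Loss of LRWD1 as the whole cause is argued against by their median of -0.09 with siLRWD1-5 (-0.10 to -0.08 over leaving out each library) against -0.45 with siLRWD1-6. LRWD1 itself fell less with siLRWD1-5, by log2 fold changes of -2.24 against -2.72, so some gap would arise from its loss alone. The genes were also chosen as lower with siLRWD1-6 in the same data, which favours a gap. How much was not tested, and the range keeps that choice fixed. Of the 927 genes with a 3' UTR, 67 (7.2%) held ACATCGT where 23.9 were expected, a z of 9.3 against at most 5.5 in 100 draws, and the z was -9.2 with 3' UTR length and base composition in the regression (lowest of the permutations, -4.9). By the ranks of the regression the word is extended to ACATCGTA, found at base 2068 of the same transcript, also coding. In the gene set the second word was CATCGTT (z of 6.5), which is absent from LRWD1. The 55 genes with the 8-base site had a median of -0.18 with siLRWD1-6 (quartiles -0.52 and 0.10) and -0.09 with siLRWD1-5. Of them 25.5% and 27.3% were called lower, against 7.1% and 20.9% of genes without its 6-base core. Seed matches are a candidate explanation for a small part of these genes, and the cause for the rest stays open.

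Genes higher with both siRNAs were enriched for a word that is absent from LRWD1. Of the 461 with a 3' UTR, 138 held ATTACAA where 64.9 were expected, a z of 10.0 against at most 7.0 in 100 draws, and ATTACAA and TTACAAA had a z of 7.2 and 5.7 with siLRWD1-5 and of 6.5 and 7.5 with siLRWD1-6, above every permutation (4.5 and 4.8), but of -2.5 and -0.7 between the siRNAs. The draws were not matched for 3' UTR length, whereas the z values of the single comparisons come from the regression with it. Lower levels of seed-matched genes in the scrambled libraries may therefore account for part of this set, a hypothesis that the sequence of the scrambled siRNA would test. They do not account for the excess sharing as a whole. With a word of this site 195 genes were shared where independent lists would share 99.1 (ratio 1.97), and without one 266 against 122.5 (ratio 2.17). A response to loss of LRWD1 and one to the shared controls cannot be told apart in the rest of this set: among genes with none of the 3 sites, 223 were higher with both where independent lists would share 100.9, but both comparisons use the same 3 control libraries.

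For each pair of groups, the 10 possible splits of 6 libraries are too few for a share under 0.05. The real split gave 5292 genes for siLRWD1-5, 2265 for siLRWD1-6 and 5919 between the siRNAs, and the highest other splits gave 0, 1 and 0. For genes changed alike with both siRNAs, 2 of 100 splits of the 9 libraries gave as many as the real 819, the real one included, and the rest gave 0. This argues against an arbitrary grouping of the libraries as the source of the count. It does not show that the sharing exceeds chance, since splits with hardly any calls have nothing to share. The other split was the split with the siLRWD1-5 libraries in the place of the controls, which gave 3047 genes and points to a structure of the samples: the siLRWD1-5 libraries stood farther from the other groups than these did from each other.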

How the results depend on the processing

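The alternatives were set before the data were examined, except no scaling beyond library size and a fit of only the libraries numbered 1 and 3 of each group, which were chosen after seeing the data. Of 248 values, those of genes open to naming by the rule and of called lists, 226 kept their direction and their side of the threshold in every alternative that gave a value, 20 lost the threshold in some, 2 gained it and 0 reversed; the cause of these changes was not tested. LRWD1 stayed between -2.27 and -2.19 with siLRWD1-5 and between -2.78 and -2.61 with siLRWD1-6 over leaving out each library. Over the same fits, siLRWD1-6 gave 702 to 2115 higher and 546 to 1838 lower genes, both siRNAs 304 to 966 higher and 169 to 784 lower, and 196 to 685 were opposite. Lists called ranged from 4 to 10 for siLRWD1-5 and from 5 to 14 for siLRWD1-6, and the correlation of fold changes from 0.111 to 0.241. The highest counts came without scrambled replicate 2, which differed most from its group, and the lowest counts for siLRWD1-6 came with fewer siLRWD1-6 libraries. Fitting only the groups compared gave 696 lower genes for siLRWD1-6, 186 lower with both and 227 opposite, with fewer libraries to estimate the spread. The correlation was 0.352 with no filter on low counts and 0.311 with DESeq2, which was also run without that filter, so both cover more genes. On the filtered genes limma-voom gave 0.133. For DESeq2 the tool and the gene set were not told apart. Camera with an estimated correlation called 0 lists for siLRWD1-5 and 1 for siLRWD1-6, and fry called 7 and 7. The labels number the libraries as series but do not state that a number marks a shared batch. Libraries sharing a number had deviations correlated between 0.05 and 0.37, and libraries with different numbers between -0.33 and 0.14. The main fit does not treat them as pairs because the labels do not state the authors' model. The lowest same-number value also lay under the bound of 0.1 used for a pair. Between scrambled and siLRWD1-5 libraries alone the same-number values were 0.25, 0.37 and 0.11. As a hint from the data, 8 of 9 libraries correlated best with a library of their own number, so a shared experiment stays possible. With the replicate block, siLRWD1-5 gave 2887 higher and 3038 lower genes, siLRWD1-6 1472 and 1343, both siRNAs 612 and 439, opposite 521, and 5 and 8 lists were called. EWSR1 with siLRWD1-5 (-0.15) passed the threshold in that fit, and FLI1 with siLRWD1-6 in it (0.22) and without scrambled replicate 2 (0.30). With number 2 left out of every group, siLRWD1-6 gave 1933 higher and 1646 lower genes, both siRNAs 893 and 649, opposite 604, the correlation was 0.186, FLI1 with siLRWD1-6 passed (0.25), and 10 and 14 lists were called, as many as without scrambled replicate 2 alone. The mitosis list had a median of -0.79 in scrambled replicate 2 relative to its group, and of -0.16 and -0.04 in the siLRWD1-5 and siLRWD1-6 libraries of that number. In simulated counts for siLRWD1-5 with 200 changed genes, recovery was 58.2% at a log2 change of 0.5, so genes that missed the threshold may still have changed. The real comparison called 5292 genes, so its own recovery may differ from the simulated one.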

Other observations

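The word counts for single genes and lists given here were made only after the words were seen. Between the siRNAs, lists without a call still held genes that differed. VEGFA, encoding a vascular growth factor, was 3.52-fold higher with siLRWD1-6 than with siLRWD1-5 (adjusted p = 5.6e-08, edgeR), and P4HA2, a collagen prolyl hydroxylase of the same hypoxia list, 2.14-fold lower. In the MAPK response list the ETS factor genes ETV5 and ETV1 were 3.35-fold and 2.06-fold higher with siLRWD1-6. TIMP2 was 5.05-fold lower with siLRWD1-6 and the cadherin gene CDH11 1.64-fold higher. In the cholesterol list MSMO1 was 4.78-fold higher and SC5DL 2.13-fold lower with siLRWD1-6. The mitosis gene CDC20 was 4.13-fold higher and the DNA damage response gene MDC1 2.43-fold higher. The histone methyltransferase gene SETD8 was 2.71-fold higher. Each is among the 4 members of its list with the smallest p.

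The annotated 3' UTR of FLI1 held 2 copies of the 7-base words linked to siLRWD1-5 and 0 of its 8-base site. Of the 38 EWS-FLI1-activated genes with a 3' UTR, 11 held a word, with a median log2 fold change with siLRWD1-5 of -0.55, and the others had a median of -0.41. Of the 29 oxidative phosphorylation genes with a 3' UTR, 6 held a word, with a median of -0.14 against -0.19 for the others. In the ATF4 and amino acid response list, 2 of 34 genes held a word linked to siLRWD1-6. Among the genes named for siLRWD1-5, 6 of the 8 lower ones with a 3' UTR held a word (PRDX3, NGFR, CMC2, GGCT, EI24 and ARL6IP6), and for siLRWD1-6 4 of 7 did (MFSD1, ANKH, CDCA7L and CMTM6). Over all genes with a 3' UTR the shares were 24.9% and 3.5%. CLDN11, KYNU and TNFAIP2, named as higher with siLRWD1-5, also held a word linked to it. PLS3, lower with both, held 1 copy of each 8-base site.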
